A study of Mus musculus with 6 samples.

How the data were processed

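The measurement was the position and number of RNA 5′ ends in whole testes of C57BL/6 mice aged 6 weeks that were heterozygous (het) or homozygous (hom) for a knockout of Rnf17, per the labels. 6 libraries were analysed, 1 per group: total testis RNA, RNA from a MIWI immunoprecipitate (MIWI IP) and RNA from a MILI immunoprecipitate (MILI IP), each from het and hom testes. MIWI and MILI are the PIWI proteins made by Piwil1 and Piwil2. Groups were read from the sample titles and source names. The antibody field of the labels gave no antibody for the het MIWI IP and named MIWI antibodies for both MILI IPs, and in these 3 cases the titles and source names were followed. The labels do not say which part of Rnf17 was deleted.

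Per the labels, polyadenylated RNA was purified, an RNA linker was ligated to free 5′ ends, cDNA was primed with random hexamers, and PCR products were selected by size on a gel (5′RACE). No step that removes 5′ caps is described there, and T4 RNA ligase joins a linker to ends that carry a 5′ monophosphate, such as those left by cleavage. The titles of the total libraries mention small and large fractions and those of the IP libraries do not, so the size selection is not known to be the same in IP and total.

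Per the submitters' processing notes, reads were placed on the mouse genome mm9, with Bowtie and STAR named. Their versions, roles and order are not given in the sources used here. The deposited files hold read counts of collapsed sequences with other fields of position and annotation: per the file headers each line is 1 placement of 1 sequence, with the rank and read count of the sequence, its number of placements, chromosome, start, end, strand, and the genes, piRNA clusters, repeats, miRNA hairpins or structural RNAs that it overlaps. Every listed placement carried an annotation, so introns and unannotated intergenic positions were not analysed here. Placements were ungapped, so reads across splice junctions were not analysed here. Sequences themselves were not used here, and the bases at positions 1 and 10 of reads were not analysed. Starts were taken to count from 0, which was checked on the mitochondrial chromosome: the 5′ end of mt-Tl1 at base 2676 held 4575 reads of the het total library, against 45 reads at the next most frequent base within 5 nt. A GENCODE annotation was used only for that check and a RefSeq table only for gene synonyms.

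Reads in the files numbered 25895168 in het total, 22514168 in hom total, 1160653 in het MIWI IP, 2400746 in hom MIWI IP, 1867029 in het MILI IP and 2277466 in hom MILI IP. Read counts never rose with rank. If the ranks number all sequences of a library in falling order of read count, which the labels do not state, the ranks missing from a file give a lower bound on the reads of the whole library, from at least 2594457 in het MIWI IP to at least 39425535 in het total. Reads with 1 placement made up 80.0% (het total), 71.6% (hom total), 47.3% (het MIWI IP), 44.2% (hom MIWI IP), 56.0% (het MILI IP) and 46.7% (hom MILI IP) of the reads.

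Gene values were counted from reads with 1 placement in sense of an exon of 1 gene. Such reads numbered 11095007 (het total), 10690212 (hom total), 209911 (het MIWI IP), 512830 (hom MIWI IP), 146902 (het MILI IP) and 246191 (hom MILI IP). Reads that overlapped exons of several genes, at most 0.329% of the reads with 1 placement in sense of an exon, were left out. Values are reads per 1000000 gene-assigned reads (RPM). The value that a count of 0 allows (3 reads) was 0.270 and 0.281 RPM in the total libraries, 14.3 and 5.85 RPM in the MIWI IPs and 20.4 and 12.2 RPM in the MILI IPs, het before hom. Reads without molecular identifiers are not independent molecules, and every interval and floor below covers counting error only.

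The 3 comparisons of genotype were hom against het in total RNA, in the MIWI IP and in the MILI IP. For each gene with at least 100 reads in both libraries together, the ratio of hom over het RPM was given with its exact 95% interval (Clopper-Pearson on the split of the reads). A gene, cluster, repeat or window was called higher or lower when the ratio passed 2-fold and the interval excluded 1. Genes that rise or fall here do so in 5′ end reads, which need not follow RNA level. With 1 library per group there was no replicate spread to test against and no p-value was computed, so a call states a difference between 2 libraries and not between conditions. Since most genes compared lay on 1 side of 1, ratios were also read relative to the median of the ratios of genes with at least 10 reads in each library.

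The genes named were fixed by rule before the data were examined. Rnf17 came first, then Dgcr8, Piwil1 and Piwil2. For each comparison the rule took the 12 genes with the highest lower bound and the 12 with the lowest upper bound of the interval, among genes with at least 10 distinct 5′ ends in the higher library and no single end above 50% of its reads. It also took the list members with most reads, the 10 genes most enriched in each IP over its total library, and the 5 single 5′ ends with most reads in each library. Clusters, repeat subfamilies, hairpins and exons named below were chosen after their values were seen.

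15 gene lists were fixed before the data were examined: piRNA pathway, genic piRNA precursors, elongating spermatid, round spermatid, meiosis and spermatocyte, spermatogonia, Sertoli cell, Leydig cell, peritubular, vascular, immune and blood cells, p53 and DNA damage, interferon response, cytosolic ribosomal proteins, mitochondrially encoded genes, Drosha-cleaved mRNA (Dgcr8) and core RNA decay. A list with at least 3 members compared was summarised by its median log2 ratio (pseudocount 0.5 RPM) and the percentile of that median among 10000 random lists of as many genes, drawn within 50 bins of read level. The value of 1 list member is not reported here.

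For the composition of a library, each read was divided evenly over its placements, and each placement was put in 1 class in the order structural RNA, miRNA hairpin, piRNA cluster sense and antisense, coding sequence (CDS), 3′UTR, 5′UTR, noncoding exon, transposon sense and antisense, exon antisense, other. Clusters, windows, transcript parts and lengths were counted from reads with 1 placement, and repeat families from divided reads. Inserts of 24 to 32 nt are called piRNA-sized here, and a separate count took inserts of at least 40 nt. The name refers to the insert only, because with random hexamer priming an insert can be shorter than its RNA. Windows of 10 kb left out sense exons of coding genes, and the 20 windows with most reads in the het library and the 20 with most in the hom library of a comparison were compared. Pairs of 5′ ends on opposite strands were counted at each overlap from 1 to 30 nt over distinct ends of all placements, and the count at 10 nt was divided by the mean of the other 29 overlaps. Shared 5′ ends between libraries were counted over distinct ends with 1 placement and set against the same count after a shift of 50 nt.

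The calling, interval and list steps were tested on simulated gene counts with 200 changed genes per comparison. Counts were drawn with counting error only (Poisson), which the intervals also assume, and without PCR copies. Changed genes had at least 200 expected reads in both libraries together. The test therefore checks the code and does not show how the rule fares on real reads. In each of the 3 comparisons the rule recovered 50 of 50 genes changed 3-fold, 50 of 50 changed 6-fold and 50 of 50 changed 10-fold, and it called 0 of 50 (total), 1 of 50 (MIWI IP) and 0 of 50 (MILI IP) genes changed 1.5-fold. Unchanged genes called numbered 1, 1 and 0 in the same order. The intervals held the true ratio for 95.7%, 96.2% and 96.6% of the genes tested.

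The alternatives tried were another gene scaling, distinct 5′ ends in place of reads, the most covered end of each gene left out, reads on either strand, all placements, other read minimums (20 and 500), other folds (1.5 and 4), other pseudocounts (0.1 and 2 RPM), windows of 5 kb, ends with at least 2 reads, libraries thinned to the shallowest, 1 placement only, insert length classes, other denominators, and reads with no piRNA cluster or repeat label. Distinct ends level off in genes with many reads for their length, so ratios by distinct ends can understate a difference there. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.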

Results

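Rnf17 5′ ends were fewer in the hom than in the het total library. Rnf17 (chromosome 14, 57021505 to 57143793, mm9, plus strand) had 7146 reads in het total and 1161 in hom total, a fall from 644 to 109 RPM with a hom over het ratio of 0.169 (95% interval 0.158 to 0.179). In the MIWI IP the gene fell from 96 to 48 reads, with a ratio of 0.205 (0.142 to 0.292). In the MILI IP it had 17 reads in each library, and the ratio of 0.597 (0.286 to 1.24) left a difference not detectable at this depth. Reads of the hom total library fell in 33 of the 37 Rnf17 exons seen. Across the 21 exons with at least 50 het total reads the ratio ran from 0.0893 in exon 7 to 0.496 in exon 14, with a median of 0.180. Since the labels do not give the deleted part of the gene, which of the remaining reads check the genotype label is unknown.

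Per gene-assigned read, Dgcr8, whose mRNA is cleaved by Drosha, changed less than 2-fold in total RNA. The genes of both PIWI proteins had ratios within 2-fold in all 3 comparisons. Dgcr8 (chromosome 16, 18254073 to 18284818) had a ratio of 0.689 (0.657 to 0.722) in total RNA, and 1 end held 40.6% of its het total reads. Its counts were 7 and 19 reads in the MIWI IPs and 18 and 18 in the MILI IPs, het before hom. The ratios there, 1.11 (0.447 to 3.13) and 0.597 (0.293 to 1.22), left a change beyond 2-fold open. Piwil1 (chromosome 5, 129242083 to 129261349) had ratios of 0.599 (0.585 to 0.612) in total, 0.649 (0.563 to 0.750) in the MIWI IP and 0.796 (0.551 to 1.15) in the MILI IP. Piwil2 (chromosome 14, 70772267 to 70828927) had ratios of 0.536 (0.519 to 0.554), 0.868 (0.681 to 1.11) and 0.839 (0.720 to 0.978) in the same order. A single end held 40.9% of the het total reads of Piwil1 and 30.97% of those of Piwil2. Relative to the median gene, Piwil1 (0.4705) and Piwil2 (0.422) were lower by over 2-fold in total RNA and Dgcr8 (0.541) was not. Piwil1 without its most covered end (0.4695) and Piwil2 without reads that carry a cluster or repeat label (0.445) passed 2-fold as well, while Piwil2 without its most covered end (0.659) moved towards 1. By distinct ends the total RNA ratio was 0.877 for Piwil1 and 1.16 for Piwil2, the latter on the other side of 1.

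Reads in sense of piRNA clusters took a smaller share of every hom library than of its het counterpart. The share was 34.6% in het total and 17.4% in hom total, a ratio of 0.504 (0.504 to 0.505). It was 34.9% and 25.6% in the MIWI IPs, a ratio of 0.734 (0.730 to 0.737), and 62.2% and 44.6% in the MILI IPs, a ratio of 0.717 (0.715 to 0.719). None of the 3 ratios passed 2-fold per annotated read. Per gene-assigned read the cluster ratios were 0.443, 0.618 and 0.4996, so that the total and MILI values reached 2-fold on that scale.

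Coding sequence and transposon reads took larger shares of the hom libraries. CDS reads made up 29.8% of het total and 36.9% of hom total, 19.3% and 23.9% of the MIWI IPs, and 5.66% and 9.82% of the MILI IPs. Transposon sense reads made up 9.24% and 13.9% of the total libraries, 17.2% and 21.0% of the MIWI IPs, and 14.1% and 20.8% of the MILI IPs, and transposon antisense reads had ratios of 1.41, 1.22 and 1.46. Per gene-assigned read the transposon sense ratios were 1.32, 1.03 and 1.03. Structural RNA was higher in hom total by a ratio of 2.36, and its rRNA reads numbered 31811 in het total and 93719 in hom total. The same class had ratios of 0.536 in the MIWI IP and 0.876 in the MILI IP. Reads on miRNA hairpins had ratios of 0.778 in total, 1.03 in the MIWI IP and 1.204 in the MILI IP, and the MILI value lay below 1 per gene-assigned read (0.839). Of hairpin reads with 1 placement, mmu-mir-130b held 247 of 333 and 550 of 754 in the MIWI IPs, het before hom. It held 353 of 469 and 510 of 658 in the MILI IPs, against 113 of 20990 in het total.

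**Figure D1:**
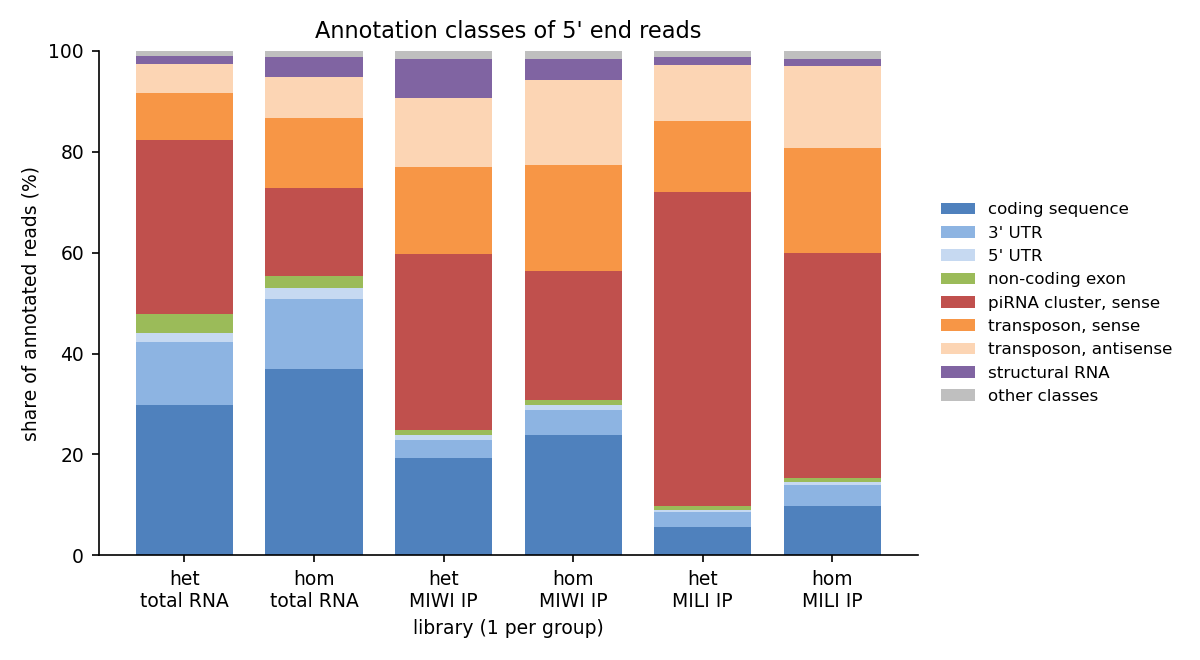
Share of annotated reads (%) in each annotation class, stacked, for the 6 libraries (1 per group). Reads in sense of piRNA clusters made up 34.6% of het total and 17.4% of hom total, 34.9% and 25.6% of the MIWI IPs, and 62.2% and 44.6% of the MILI IPs.

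The most abundant cluster inserts were 24 to 28 nt long, depending on the library. Insert length need not be RNA length, since cDNA was primed with random hexamers. Cluster sense reads peaked at 28 nt in het total and in the het MIWI IP, at 26 nt in hom total and in the hom MIWI IP, and at 24 nt in both MILI IPs. Inserts of 24 to 32 nt made up 61.0% of cluster reads in het total and 48.5% in hom total, 66.7% and 64.1% in the MIWI IPs, and 43.7% and 43.1% in the MILI IPs. Inserts of at least 40 nt made up 16.3% of cluster reads in het total and 30.1% in hom total. Coding sequence reads were longer, with 80.6% (het total), 78.1% (hom total), 80.0% (het MIWI IP), 79.4% (hom MIWI IP), 54.2% (het MILI IP) and 67.8% (hom MILI IP) of at least 40 nt.

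Among piRNA-sized inserts alone, clusters also took less in hom and transposons took more. Cluster sense reads were 78.8% of piRNA-sized reads in het total and 48.2% in hom total, 81.9% and 64.0% in the MIWI IPs, and 87.6% and 72.0% in the MILI IPs. Transposon sense reads were 2.71% and 13.0% in total, 1.26% and 11.6% in the MIWI IPs, and 1.95% and 10.2% in the MILI IPs, which are ratios of 4.80, 9.19 and 5.26. Coding sequence was 9.21% and 19.1% in total, 5.26% and 7.68% in the MIWI IPs, and 3.22% and 4.72% in the MILI IPs. Among inserts of at least 40 nt the cluster share had ratios of 0.799 in total, 0.855 in the MIWI IP and 0.590 in the MILI IP.

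**Figure D2:**
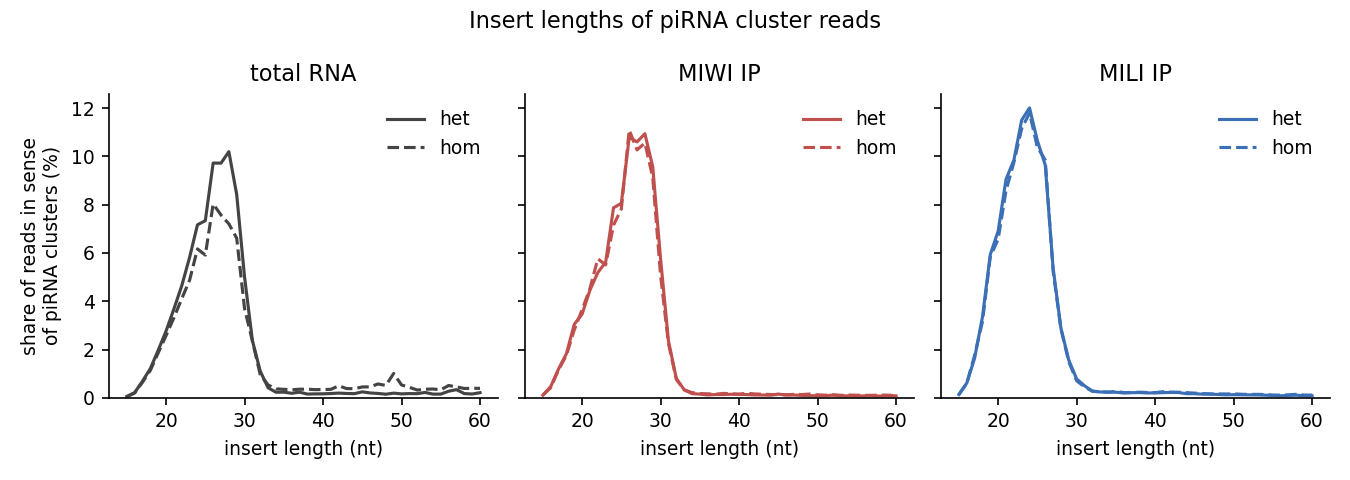
Insert length (nt) of reads in sense of piRNA clusters, as a share (%) of those reads, with 1 panel per sample type and 1 line per genotype. The peak lay at 28 nt in het total, 26 nt in hom total and 24 nt in both MILI IPs, and the 24 to 32 nt range held 61.0% of het total and 48.5% of hom total cluster reads.

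Single piRNA clusters went in both directions. Cluster 17-qA3.3-27363.1 (chromosome 17, 27425201 to 27461998), with 503110 reads in het total, had hom over het ratios of 0.471 in total, 1.015 in the MIWI IP and 0.778 in the MILI IP. Cluster 2-qE1-35981.1 (chromosome 2, 92381298 to 92439261) had ratios of 0.465, 0.769 and 0.841 in the same order. Larger falls were seen at 5-qG3-23659.1 (chromosome 5, 150592654 to 150627945), with 0.199, 0.252 and 0.325, and at 7-qD1-19431.1 (chromosome 7, 80250188 to 80271444), with 0.160, 0.183 and 0.261. Cluster 10-qB4-6488.1 (chromosome 10, 62114441 to 62164295) had ratios of 1.77, 2.24 and 2.34. Cluster 17-qE1.1-7037.1 (chromosome 17, 66556140 to 66581085) had 1.80, 2.24 and 1.59, and its MILI value lay below 1 per gene-assigned read (0.963).

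Of the 100 clusters compared in total RNA, 45 were lower and 6 were higher in hom by 2-fold, and the median ratio was 0.526. The MIWI IP had 23 lower and 14 higher clusters with a median of 0.768, and the MILI IP had 12 lower and 12 higher with a median of 0.828. Intervals lay below 1 for 79, 57 and 57 clusters and above 1 for 19, 29 and 32 in total, MIWI IP and MILI IP. Per gene-assigned read the medians were 0.425, 0.607 and 0.502, with 88, 75 and 86 clusters below 1. Per read with 1 placement, the long inserts of single clusters showed no common fall. That depends on the denominator. The scale per gene-assigned read differs from it by 1 factor per comparison, which lowered the medians of all inserts as given above. The same factors would put the medians of long inserts, given next, below 1 in every comparison. Inserts of at least 40 nt had median ratios of 1.04 over 100 clusters in total (46 with intervals below 1 and 50 above), 1.095 over 80 in the MIWI IP (28 and 34) and 1.38 over 75 in the MILI IP (17 and 42), while piRNA-sized inserts had medians of 0.464, 0.686 and 0.789. Reads antisense to clusters had ratios of 1.56, 1.55 and 1.79.

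Windows of 10 kb outside coding exons depended on the library that chose them. The 20 windows with most reads in het total held 13.5% of its reads with 1 placement and 4.74% of those of hom total, and 15 of them were lower by 2-fold. The 20 windows with most reads in the het IP went from 22.9% to 15.3% in the MIWI IPs, with 7 lower, and from 34.5% to 27.8% in the MILI IPs, with 3 lower, and windows chosen by het reads favour lower values in hom. Of the 20 windows with most hom reads, 3 were lower and 6 higher in total, 2 and 3 in the MIWI IPs, and 1 and 0 in the MILI IPs, with median ratios of 0.893, 0.946 and 0.974. The window with most het total reads (chromosome 17, 27450001 to 27460000) had 288762 reads in het and 85274 in hom, a ratio of 0.379. The window with most hom total reads (chromosome 7, 106980001 to 106990000) had 62142 and 112302 reads, a ratio of 2.32 (2.298 to 2.34), and 1 end with inserts of 15 nt on average held 112128 of the hom reads. Another on chromosome 17 (39980001 to 39990000), at Rn45s, had 25010 and 68242, a ratio of 3.505 (3.45 to 3.56).

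**Figure D3:**
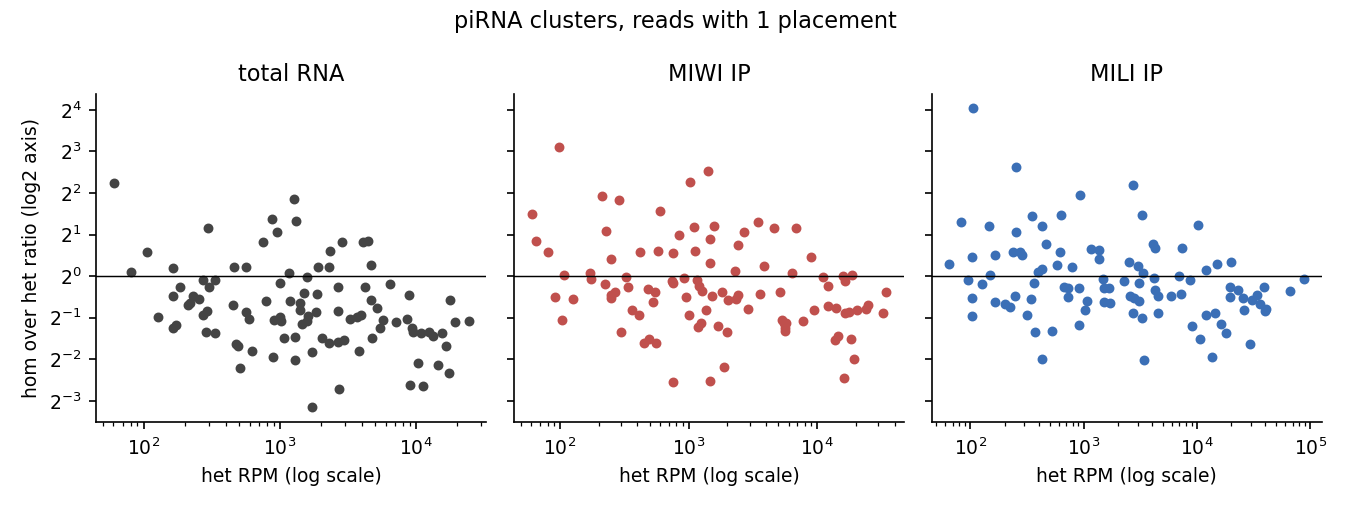
Hom over het ratio (log2 axis) against het reads per 1000000 reads with 1 placement (log axis) for 100 piRNA clusters, 1 point per cluster and 1 panel per sample type. In total RNA 79 clusters had an interval below 1 and 19 above, and the median ratio was 0.526 there, 0.768 in the MIWI IP and 0.828 in the MILI IP.

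L1 retrotransposon reads took a larger share of every hom library. Among inserts over 20 nt, L1 sense reads had ratios of 2.05 in total, 4.51 in the MIWI IP and 5.76 in the MILI IP, and per gene-assigned read 1.81, 3.80 and 4.01, so the total value passed 2-fold on 1 scale only. L1 antisense reads had ratios of 1.31, 2.27 and 2.66. Among piRNA-sized inserts the L1 sense ratios were 5.18, 10.3 and 8.69, and 4.55, 8.71 and 6.05 per gene-assigned read. All 11 L1 sense subfamilies compared at that length were higher in all 3 comparisons, with median ratios of 9.77, 39.5 and 27.7. These medians lay above the ratios of the whole L1 sense family, so the 11 need not stand for all L1 subfamilies. The 9 L1 antisense subfamilies compared at that length split into 5 higher and 4 lower in total and 5 higher and 3 lower in each IP, with medians of 6.49, 5.04 and 11.4. L1Md_A had ratios of 12.05 in total, 119 (65.5 to 244) in the MIWI IP and 28.0 in the MILI IP. L1Md_F2 had 9.40, 45.3 and 31.5, and L1Md_T had 13.4, 39.5 and 16.4. Reads with several placements were divided over them.

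Endogenous retroviruses and older repeats differed by family and by sample type. Among piRNA-sized inserts, antisense reads of IAPEz-int had ratios of 9.58, 16.1 and 3.62, and those of MERVL-int 13.6, 39.7 and 12.4, in total, MIWI IP and MILI IP. Antisense reads of MIR3 (0.146, 0.352 and 0.334) and of ORR1E-int (0.152, 0.301 and 0.388) were lower. Among inserts over 20 nt, ERVK sense had ratios of 0.745, 2.34 and 1.87, and ERVK antisense 1.12, 1.91 and 1.67, with the total antisense value below 1 per gene-assigned read (0.983). Alu sense had 1.22, 2.18 and 2.02 and B2 sense 1.33, 2.48 and 2.21. L2 antisense was lower in all 3 comparisons, with 0.436, 0.452 and 0.480. Per gene-assigned read the MILI values of ERV1 sense (0.875), ERV1 antisense (0.844), MaLR antisense (0.722), B4 sense (0.828), B4 antisense (0.850) and ID antisense (0.922) lay below 1, on the other side from their values per annotated read. Inserts of up to 20 nt made up 81.5% of transposon sense reads in the het MIWI IP, 59.02% in the hom MIWI IP, 77.2% in the het MILI IP and 59.8% in the hom MILI IP.

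5′ ends of several late spermatid genes were fewer and those of several somatic genes more frequent in hom total RNA. Tnp1 (chromosome 1, 73061648 to 73062491), which encodes a transition protein, fell from 4135 to 118 RPM, a ratio of 0.0285 (0.0270 to 0.0302) from 45880 and 1262 reads. Prm2 (chromosome 16, 10791473 to 10792201), a protamine gene, fell from 5316 to 199 RPM, a ratio of 0.0375 (0.0359 to 0.0391). By distinct ends the ratios were 0.513 for Tnp1 and 0.580 for Prm2. The 45880 het reads of Tnp1 lay on only 330 distinct ends and the 58984 of Prm2 on 591. Distinct ends level off at such depth, so these ratios cannot show the size of the difference. Sod3 (chromosome 5, 52755178 to 52760980), an extracellular superoxide dismutase, rose from 23 to 618 reads, a ratio of 27.9 (18.4 to 44.3). Clu, a Sertoli cell product, rose 7.09-fold (6.80 to 7.41) and the Leydig cell enzyme Cyp11a1 rose 10.4-fold (9.26 to 11.8).

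Of 11955 genes compared in total RNA, 3262 (27.3%) were higher and 1520 (12.7%) were lower in hom. By distinct 5′ ends 1570 were higher and 968 lower. The median gene with at least 10 reads in each library was shifted by 0.35 in log2 in total, 0.10 in the MIWI IP and 0.21 in the MILI IP. Relative to that shift 2176 genes were higher and 2278 lower in total, which moved the share of higher genes among the calls from 68.2% to 48.9%. The 12 genes with the highest lower bounds were Sod3, Ly6e (25.1, 16.2 to 40.9), Psap (12.5, 11.1 to 14.1), Gstm1 (12.2, 11.02 to 13.6), Fads2 (12.9), Lrp10 (17.6), Cx3cl1 (22.8, 10.2 to 63.3), Ecm1 (13.7), Col6a1 (14.1), Ltbp4 (15.5), Inha (12.2, 10.1 to 14.9) and Fxyd1 (15.4). Gstm1 fell below 2-fold by distinct ends (1.95).

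The 12 genes with the lowest upper bounds in total RNA included Tnp1 and Prm2. 1700061I17Rik fell from 443 to 3 reads, with a ratio of 0.00703 (0.00144 to 0.0207). Cyp2a12 fell from 273 to 1 read, with 0.00380 (9.59e-05 to 0.0214), and Slc22a12 from 135 to 1 read, with 0.00769 (0.000193 to 0.0436). The neighbouring paralogs Smok2b (0.0121) and Smok2a (0.0128) on chromosome 17 fell as well, and reads were not checked for placement on the wrong copy, and 1700027A15Rik (0.0383) lay next to Tnp1. The others were 1700029B22Rik (0.00977), 4933402N03Rik (0.0166), 4930432J09Rik (0.0234) and Gm8633 (0.0262). Reads free of a repeat or cluster label were 200 of the 425 het reads of 1700029B22Rik, 9 of the 488 of 4930432J09Rik and 127 of the 357 of Gm8633.

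Spermatid and spermatocyte lists had medians below 0 in total RNA, and spermatogonia and somatic lists had medians above 0. Of 26 elongating spermatid genes compared 0 were higher, 15 lower and 11 neither, with a median log2 of -1.42 (percentile 0 among random lists), and after the shift 18 were lower (median -1.76). Prm2 and Tnp1 fell while Odf2 (1.04) and Ldhc (1.33) did not. Of 24 round spermatid genes 1 was higher and 8 lower, with a median of -0.58 (percentile 0.06, 0 higher and 11 lower after the shift), and Crem fell to 0.468 while Actl7b (1.26) and Tbpl1 (1.16) stayed within 2-fold. Of 24 meiosis and spermatocyte genes 2 were higher and 7 lower, with a median of -0.40 (percentile 1.00), and after the shift 1 was higher and 8 lower (median -0.75). Sycp2 (0.320) and Psma8 (0.374) fell, and Hspa2 had a ratio of 1.83. Of 11 spermatogonia genes 7 were higher and 0 lower, with a median of 1.48 (percentile 99.8, 6 higher after the shift), and Uchl1 rose 3.53-fold while Stra8 (1.21), Id4 (0.683) and Dazl (0.996) did not pass 2-fold.

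Of 14 Sertoli cell genes 11 were higher and 0 lower, with a median of 1.77 (percentile 100.0), and after the shift 9 were higher (median 1.42). Clu, Ctsl (4.60) and Aard (2.08) rose and Tjp1 (1.02) did not. Of 12 Leydig cell genes 10 were higher and 0 lower, with a median of 2.29 (percentile 100.0, 1.94 after the shift), among them Cyp17a1 (7.10), Cyp11a1 and Hsd3b1 (4.42), while Star had 1.77. Of 10 peritubular, vascular, immune and blood genes 9 were higher and 0 lower, with a median of 2.00 (percentile 100.0), led in reads by Acta2 (7.44) and Myh11 (4.17). No gene was on 2 of the lists. Each difference rests on 1 library per genotype and has no replicate check.

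piRNA pathway genes showed no common direction in total RNA. Of 23 genes 2 were higher, 3 lower and 18 neither, with a median ratio of 0.999 (percentile 34.1), and after the shift 2 were higher and 6 lower. Tdrd6 rose 2.79-fold (2.70 to 2.88) from 5638 to 15147 reads, Ddx25 had a ratio of 1.19, and Rnf17 was 1 of the lower genes. Of 8 genic piRNA precursors 1 was higher and 3 lower, with a median log2 of -0.15 (percentile 23.3, 0 higher and 3 lower after the shift), and Asb1 (0.477), Kctd7 (0.372) and Ip6k1 (0.470) fell while Golga2 (0.973) did not. p53 and DNA damage genes split into 6 higher, 1 lower and 7 neither (median 0.46, percentile 60.3, 4 higher and 1 lower after the shift), with Mdm2 at 0.840, Zmat3 at 0.911 and Chek1 lower at 0.380. Interferon response genes split into 4 higher, 1 lower and 2 neither (median 1.07, percentile 82.4), with Bst2 (2.48) and Irf9 (2.27) higher, but after the shift 0 were higher and 1 was lower. Of 57 cytosolic ribosomal protein genes 15 were higher and 3 lower (median 0.55, percentile 85.8, 7 higher and 4 lower after the shift), and Rpl4 had 1.29, Rpl41 1.71 and Rpl13a 2.04. Of 16 core RNA decay genes 1, Cnot1 (2.15), was higher and 0 lower, with a median ratio of 1.00 (percentile 28.7, 0 higher and 0 lower after the shift), and Upf1 had 1.015. The Drosha-cleaved mRNA list held Dgcr8 alone, which was neither. The mitochondrially encoded list had 0 symbols in the gene annotation of the files and gave no value.

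**Figure D4:**
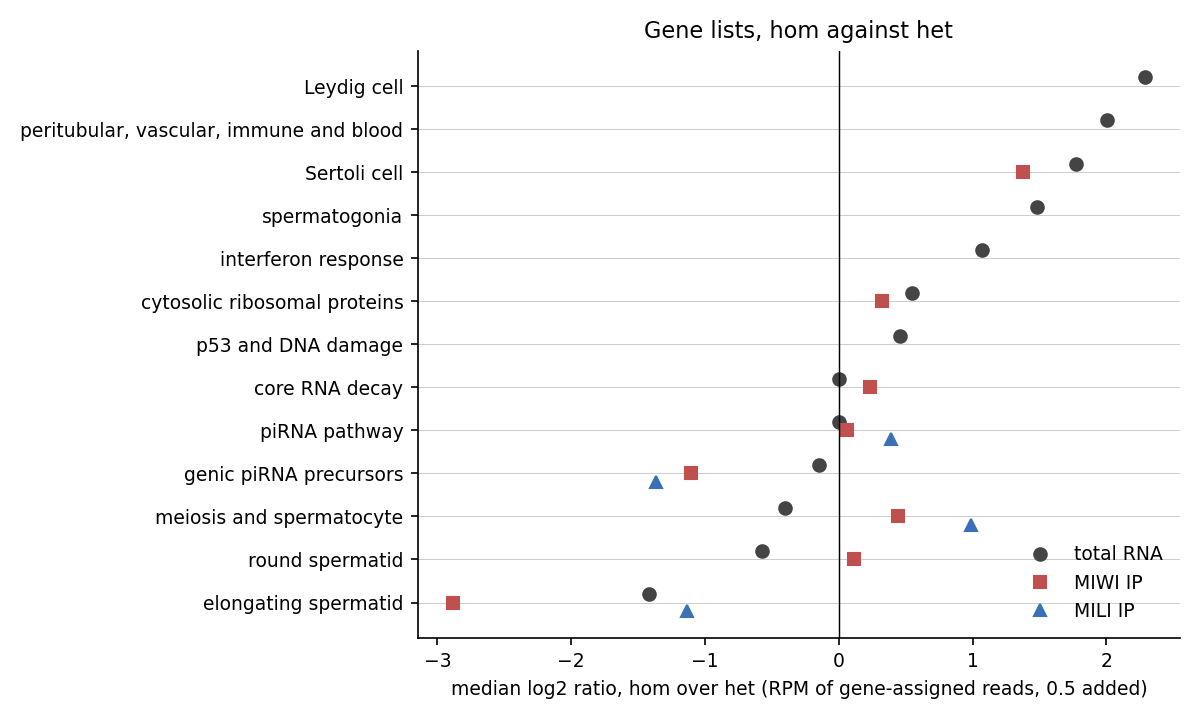
Median log2 ratio, hom over het, of each gene list with at least 3 members compared, 1 symbol per sample type. The elongating spermatid medians were -1.42 in total, -2.89 in the MIWI IP and -1.13 in the MILI IP, and the Leydig cell median in total was 2.29.

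In the MIWI IP, 5′ ends of Tnp2, Prm2 and other spermatid genes were fewer in hom. Tnp2 (chromosome 16, 10788005 to 10788786) went from 701 to 10 reads, a ratio of 0.00584 (0.00279 to 0.0108). Prm2 went from 861 to 32 reads, with 0.0152 (0.0103 to 0.0216), and Tnp1 from 191 to 13, with 0.0279. Smcp, a sperm mitochondrial capsule gene, fell from 566 to 89 reads (0.0644). Tex101, a germ cell surface protein gene, rose from 8 to 195 reads, with a ratio of 9.98 (4.96 to 23.4), and Clu rose from 126 to 1138 reads, with 3.70 (3.07 to 4.48).

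Of 1567 genes compared in the MIWI IP 132 were higher and 134 lower, and relative to the shift 101 were higher and 140 lower. By distinct ends 53 were higher and 82 lower, and with inserts of at least 40 nt alone 81 were lower. The other genes with the highest lower bounds were Stambp (6.00, 4.57 to 8.01), Exoc8 (4.56), Dcaf10 (6.78), Zyg11b (6.37), Ptgds (4.78), P4hb (4.75), Ctsl (4.01), Agt (3.85), Cst3 (5.17) and Cyp17a1 (3.65). By distinct ends Exoc8 (1.93) and Clu (1.963) fell below 2-fold, and Dcaf10 lost its call with inserts of at least 40 nt (3.36, from 2 and 17 reads). The other genes with the lowest upper bounds were Spata3 (0.0326), 4933411K16Rik (0.0397), Fam71b (0.0304), Iqcf3 (0.0370), H1fnt (0.0733), Akap1 (0.0688), 4930407I10Rik (0.0715) and Txndc2 (0.0758).

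Of 14 elongating spermatid genes compared in the MIWI IP 12 were lower, 0 higher and 2 neither, with a median log2 of -2.89 (percentile 0, -2.99 after the shift), and Odf2 fell to 0.471 while Ldhc (1.10) did not. Of 4 genic piRNA precursors 3 were lower, Asb1 (0.441), Kctd7 (0.261) and Ip6k1 (0.491), and Golga2 (1.89) was neither, with a median of -1.10 (percentile 2.01), which by distinct ends was -0.84 and left the lowest 2.5% of random lists. Of 5 Sertoli cell genes 3 were higher, Clu, Ctsl and Cst12 (2.60), with a median of 1.38 (percentile 99.99), and Aard had 1.55. Of 12 piRNA pathway genes 1, Rnf17, was lower and 0 higher (median 0.06, percentile 11.1), with Tdrd6 at 1.30 and Ddx25 at 1.09. Of 8 round spermatid genes 1 was lower and 7 neither (median 0.12, percentile 20.8), with Dkkl1 at 1.10 and Actl7b at 0.623. Of 11 meiosis and spermatocyte genes 1 was higher and 0 lower (median 0.44, percentile 87.0, 0 higher after the shift), with Hspa2 at 1.76 and Syce1 at 1.23. The 4 ribosomal protein genes (median 0.32, percentile 52.8; Rpl4 1.92, Rpl13a 1.35), the 4 core decay genes (median 0.23, percentile 31.7; Cnot1 1.23, Smg6 0.708) and the 2 p53 genes (Mdm2 1.00, Zmat3 0.850) were neither. The 1 Leydig cell gene compared, Cyp17a1, was higher, and the spermatogonia, peritubular, interferon and Dgcr8 lists had 0 genes with enough reads.

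In the MILI IP, 5′ ends of Prm2, Tnp2 and several other genes were fewer in hom. Prm2 fell from 163 to 6 reads, a ratio of 0.0220 (0.00794 to 0.0488), and Tnp2 from 93 to 9 (0.0577). 4921525O09Rik fell from 3351 to 839 reads (0.149), and each of its reads also carried a piRNA cluster or repeat label. 1700001L05Rik fell from 6124 to 2958 reads (0.288), and 5876 of the het reads carried no such label. Clu rose from 23 to 205 reads, with a ratio of 5.32 (3.45 to 8.58), and the glucose transporter gene Slc2a3 rose 3.21-fold (2.67 to 3.89).

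Of 675 genes compared in the MILI IP 122 were higher and 62 lower, and relative to the shift 69 were higher and 83 lower, which moved the share of higher genes among the calls from 66.3% to 45.4%. By distinct ends 24 were higher and 26 lower, and with inserts of at least 40 nt alone 13 and 10. The other genes with the highest lower bounds were Stk39 (4.30), Ccdc104 (3.75), Nasp (2.84), Hsp90b1 (2.92), Zfp318 (3.06), Efcab5 (3.29), Rpgrip1 (3.47), Stambp (2.81), Cebpg (3.41) and Sfmbt2 (3.42). By distinct ends Slc2a3 (1.69), Nasp (1.61) and Hsp90b1 (1.87) fell below 2-fold, and with inserts of at least 40 nt Nasp (1.963) and Efcab5 (1.84) did. The other genes with the lowest upper bounds were 4933411K16Rik (0.0494), Wdfy3 (0.156), 4930525D18Rik (0.163), Smcp (0.204), Arhgap20 (0.241), 4933440M02Rik (0.274), Maz (0.253) and 1700006A11Rik (0.308). Het reads free of a repeat or cluster label were 5 of 448 for Wdfy3, 0 of 547 for Arhgap20 and 1 of 3135 for 1700006A11Rik, whose ratio among inserts of at least 40 nt was 1.40. By distinct ends Arhgap20 (0.541), 1700001L05Rik (0.596) and 1700006A11Rik (0.599) stayed within 2-fold, and with inserts of at least 40 nt Arhgap20 (0.741) and 1700001L05Rik (0.632) did. Wdfy3 lost its call without labelled reads (0.321).

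Of 4 genic piRNA precursors compared in the MILI IP all were lower, Asb1 (0.395), Kctd7 (0.287), Ip6k1 (0.429) and Golga2 (0.381), with a median log2 of -1.36 (percentile 3.35). Of 8 elongating spermatid genes 4 were lower and 0 higher, with a median of -1.13 (percentile 0.07, -1.34 after the shift), and Odf2 (1.10), Ldhc (1.37) and Meig1 (1.91) were neither. Of 7 piRNA pathway genes 1, Tdrd6 (2.20), was higher and 0 lower (median 0.39, percentile 47.0), and after the shift 0 were higher. Of 5 meiosis and spermatocyte genes 2 were higher and 0 lower (median 0.99, percentile 96.9, 1 higher after the shift), with Syce1 at 2.09, Hspa2 at 1.83 and Stag3 at 1.49. The Sertoli cell gene Clu was higher. The 2 round spermatid genes Tbpl1 (1.44) and Dkkl1 (1.46), Zmat3 of the p53 list (0.884), Rpl4 (1.27) and Cnot1 (1.74) were neither. The spermatogonia, Leydig, peritubular, interferon and Dgcr8 lists had 0 genes with enough reads.

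Lower genes were shared between sample types by a wider margin over independence than higher genes. Among genes compared in both, 61 were lower in total and in the MIWI IP against 12.3 if the calls were independent, and 52 were higher in both against 29.2. Total and the MILI IP shared 30 lower genes against 4.17 and 31 higher genes against 26.6. The IPs of MIWI and MILI shared 27 lower genes against 2.70 and 14 higher genes against 6.28. The largest margin possible falls as calls become more common. Among the 1564 genes compared in total and in the MIWI IP, 346 were higher and 146 lower in total. The overlap was not counted for calls relative to the shift, so the contrast may only reflect how common the calls were.

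Some histone genes, whose mRNAs as a class lack poly(A) tails, were among the genes most enriched in the IPs over total RNA. Histone genes were not a fixed list, and the others were not counted. None of the 6 libraries was a control IP. Binding was not separated from a difference in poly(A) purification between IP and total. Hist1h2ba (chromosome 13, 24025618 to 24026061) had 400.2 RPM in the het MIWI IP and 3.42 RPM in het total, a ratio of 117 (78.8 to 176). Hist1h1t had ratios of 68.1 in the het MIWI IP, 111 in the hom MIWI IP, 57.6 in the het MILI IP and 105 in the hom MILI IP. Hist1h1a had 32.3, 53.2, 152 and 157 in the same order. The hairpin gene Mir130b (chromosome 16, 17124164 to 17124226) had ratios of 58.5 in the hom MIWI IP, 236 (190.4 to 294) in the het MILI IP and 113 in the hom MILI IP. In the het MIWI IP its ratio was 116 (92.1 to 146), but 1 end held 55.5% of its reads there, which kept it out of the first 10.

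Further genes in the first 10 of the het MIWI IP were Lars2 (21.9), 4930432K09Rik (19.6), Pacs1 (14.4), B230312A22Rik (14.3), the rRNA precursor Rn45s (14.1), Git1 (13.4) and Atg9a (13.2). In the hom MIWI IP they were Hist1h2ba (90.2), Ptgds (28.2), C7 (8.77), Hist3h2a (6.90), Lars2 (6.36), 4930432K09Rik (6.22) and 9230104L09Rik (5.99). In the MILI IPs they were Fbxo41 (65.9), Cmtm4 (49.2), Traf3 (33.7), Map3k9 (32.9), Klf13 (31.3), Neurl1b (31.2) and Lars2 (29.95) in het, and Hist1h2ba (59.3), Stxbp4 (21.1), Zbtb3 (19.3), Cmtm4 (18.4), Elfn2 (17.2), Snx30 (14.6) and Tfcp2l1 (14.5) in hom. Inserts of at least 40 nt were 4.17% of the Fbxo41 reads of the het MILI IP and 3.16% of the Zbtb3 reads of the hom MILI IP, against 83.3% of the Hist1h2ba reads of the het MIWI IP. Size selection is not known to have been the same in IP and total, so enrichment in an IP and a difference in insert size were not separated. The het MIWI IP had 1032 genes higher (648 by median of ratios scaling and 640 by distinct ends) and 1801 lower than total among 9459 compared, and the hom MIWI IP 492 and 2366 among 10381. The het MILI IP had 1108 higher and 1984 lower among 9460, and the hom MILI IP 781 and 1802 among 10347. The ratio of hom to het enrichment had a median log2 of -0.25 over 2101 genes for MIWI (quartiles -0.89 and 0.35) and -0.17 over 1274 genes for MILI (quartiles -0.84 and 0.45).

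The coding sequence held most 5′ ends of coding genes in every library. It took 66.4% of such reads in het total and 69.2% in hom total, 80.2% and 79.9% in the MIWI IPs, and 61.2% and 67.0% in the MILI IPs. The 3′UTR took 29.8% and 26.9% in total, 16.3% and 16.96% in the MIWI IPs, and 34.9% and 29.4% in the MILI IPs. The 5′UTR took between 3.12% in the hom MIWI IP and 3.93% in the het MILI IP. Among inserts of at least 40 nt the coding sequence share was 72.8% in the het and 73.0% in the hom MILI IP.

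Opposite-strand 5′ ends overlapped by 10 nt more often than by the mean of other lengths in all 6 libraries when all placements were counted. The count at 10 nt over the mean of the other overlaps was 1.87 in het total and 2.38 in hom total, 1.61 and 3.60 in the MIWI IPs, and 1.53 and 3.001 in the MILI IPs. Its z scores over the other overlaps were 14.6 and 15.9, 2.13 and 8.83, and 2.09 and 6.79. An overlap of 10 nt was the most frequent in 5 of the libraries, and in the het MILI IP the most frequent was 17 nt. With libraries thinned to the shallowest the values were 3.62 and 4.28 in total, 4.24 in the hom MIWI IP and 3.34 in the hom MILI IP. With 1 placement alone the het MILI IP had 0.974. Among inserts of 24 to 32 nt the values were 2.67 in het total, 3.38 in hom total, 4.00 in the hom MIWI IP and 3.39 in the hom MILI IP. The het IPs had little or no excess at that length, with 1.33 (z 0.34) for MIWI and 1.04 (z 0.05) for MILI. Weighted by reads, the 4 IP ratios lay below 1, from 0.0345 in the het MILI IP to 0.192 in the hom MIWI IP.

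**Figure D5:**
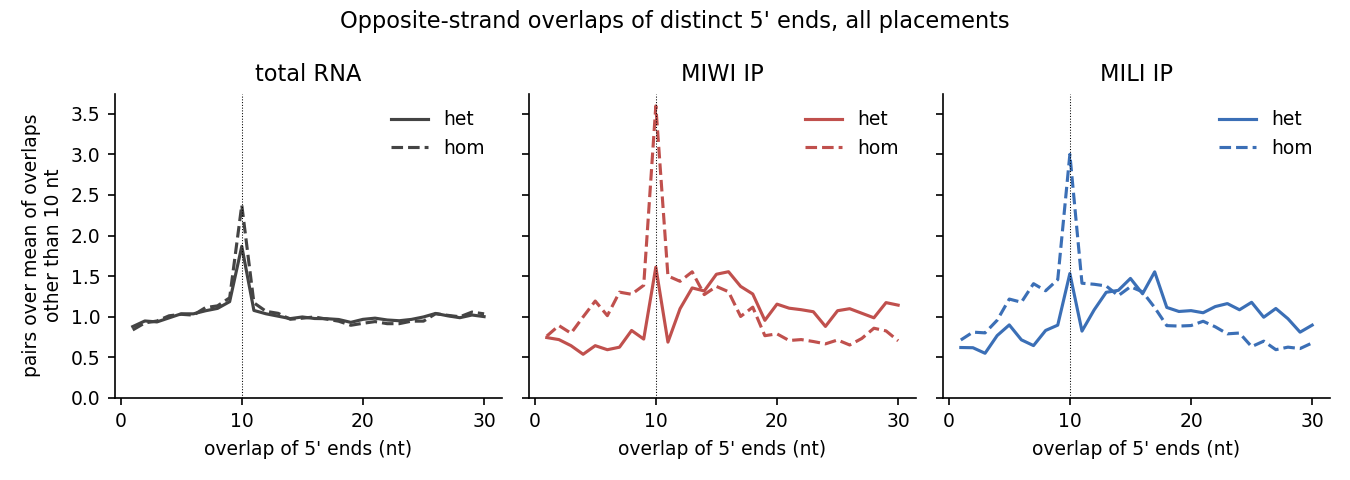
Pairs of distinct 5′ ends on opposite strands at each overlap (nt), over the mean of the overlaps other than 10 nt, with 1 panel per sample type and 1 line per genotype. At 10 nt the value was 1.87 in het total and 2.38 in hom total, 1.61 and 3.60 in the MIWI IPs, and 1.53 and 3.001 in the MILI IPs.

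5′ ends of an IP lay at the same base in the total library of its genotype more often than after a shift, by a share that depended on depth. The share was 62.7% (62.5 to 62.9, Wilson) of distinct ends for the het MIWI IP, against 29.2% after a shift of 50 nt, and 61.2% against 29.6% for the hom MIWI IP. It was 57.2% against 23.003% for the het MILI IP and 55.1% against 24.6% for the hom MILI IP. With all libraries thinned to the shallowest the shares were 20.6% and 19.2% for the het and hom MIWI IPs and 22.3% and 18.5% for the MILI IPs. At full depth these ends held 83.4%, 80.2%, 89.0% and 82.9% of the reads of the 4 IPs. Between genotypes, 40.2% of het total ends lay in hom total (21.0% shifted), 30.4% of het MIWI ends in the hom MIWI IP (6.69% shifted) and 32.4% of het MILI ends in the hom MILI IP (5.91% shifted). Between the proteins, 19.9% of het MIWI ends lay in the het MILI IP (3.65% shifted) and 17.3% of hom MIWI ends in the hom MILI IP (3.82% shifted). At 24 to 32 nt and from 40 nt the shares between genotypes were 35.3% and 38.1% in total, 41.9% and 22.9% in the MIWI IPs, and 38.3% and 17.1% in the MILI IPs. Those between the proteins were 39.5% and 7.29% in het and 28.2% and 10.3% in hom. With ends carrying 1 read making up 65.3% to 81.1% of the ends of a library, these shares depend on depth.

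Single 5′ ends took up to 3.39% of the reads with 1 placement. An end inside an L1MA5 repeat (chromosome 7, 106984173, minus strand), with inserts of 15 to 16 nt on average, came first in hom total with 112128 reads (0.695%) and in all 4 IPs, with 16295 reads (2.97%) in the het MIWI IP, 35997 (3.39%) in the hom MIWI IP, 19490 (1.86%) in the het MILI IP and 32528 (3.06%) in the hom MILI IP. The het total library began with 2 neighbouring ends of Snord82 (chromosome 1, 88252903 and 88252902), with 95531 and 93017 reads, then ends of 4930525D18Rik (chromosome 9, 114265008, 86878 reads) and of cluster 5-qG3-23659.1 (chromosome 5, 150610671, 73115 reads). Hom total continued with Snord49a (44891 reads), Rn45s (44435 reads) and both Snord82 ends. In the IPs the next ends lay in an L2a repeat (chromosome 10, 38809777, 6918 reads in the het MIWI IP), an L1ME4a repeat (chromosome 11, 75198460, in all 4 IPs) and piRNA clusters such as 17-qA3.3-26735.1 (chromosome 17, 27494278, 7115 reads in the het MILI IP). Inserts at these ends were also short, with means of 17 nt (L2a), 18 nt (L1ME4a) and 19 nt (17-qA3.3-26735.1).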

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

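All tests in this part except that on sequences with many placements were chosen after the result was seen. With 1 library per genotype, a difference between mice, preparations or sequencing runs cannot be told apart from genotype in any pattern here.

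Reads in sense of piRNA clusters took a smaller share of the hom libraries. Fewer small inserts in hom would leave the share among inserts of 24 to 32 nt level, but its ratio was 0.611 in total, 0.781 in the MIWI IP and 0.821 in the MILI IP, which argues against that as the whole cause. Scaling to annotated reads in place of all reads would leave cluster reads per library read level, but their ratio was 0.463, 0.716 and 0.631 if the ranks number every sequence of a library, and a rise of other classes stays open. A lower share of the cells that make pachytene piRNAs may be part of it, and the 19 clusters with intervals above 1 in total do not settle this, because clusters of earlier stages were not told apart from pachytene ones. A direct effect of the genotype on piRNA production was not tested and stays open.

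piRNA-sized L1 sense reads were more frequent in hom. Its ratio per annotated read was 5.18 in total, 10.3 in the MIWI IP and 8.69 in the MILI IP, which tells nothing of chance placement of sequences of up to 20 nt, since inserts of 24 to 32 nt hold none of them. Sequences with many placements alone are not the cause, since the L1 share among reads with 1 placement had ratios of 5.88, 6.85 and 6.37. Copies of a few sequences in PCR would leave the L1 share of distinct piRNA-sized sequences level at equal depth, but it was higher by ratios of 4.4, 8.68 and 6.35, and that of distinct ends with 1 placement by 2.42, 4.99 and 3.92. The L1 share among inserts of at least 40 nt had ratios of 1.29, 1.19 and 1.65, so long L1 ends differed less than piRNA-sized ones, but 5′ ends do not measure transcript level, and a higher level, more processing into piRNA-sized RNA and a difference between the mice or preparations stay open.

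Elongating spermatid ends were fewer and somatic ends more frequent in hom total RNA. Loss of elongating spermatids alone would raise all other cell types alike, but the meiosis and spermatocyte list (median log2 -0.40, upper quartile 0.08, 2 genes higher and 7 lower) and the spermatogonia list (median 1.48, lower quartile 0.55, 7 higher and 0 lower) moved apart. Scaling to gene-assigned reads moves all genes by 1 factor and leaves the place among random lists as it is, and there the elongating spermatid list lay at percentile 0 and the Sertoli and Leydig cell lists at percentile 100.0, so scaling alone is not the cause of the split. A loss that reaches spermatocytes, with the shares of spermatogonia and somatic cells rising, is a candidate explanation, and so is a change of RNA level or of 5′ monophosphate ends within cells. 5′ end reads alone do not separate these.

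The next results went in opposite directions in total RNA and in an IP, and the differences between sample types were not tested. miRNA hairpin reads had a ratio of 1.2 in the MILI IP and 0.778 in total, but per gene-assigned read the MILI value was lower in hom as well. In the IPs most hairpin reads with 1 placement came from mmu-mir-130b, so the contrast sets mainly 1 hairpin against the whole class. Structural RNA reads had 0.536 in the MIWI IP and 0.876 in the MILI IP against 2.36 in total. The round spermatid median was 0.12 in the MIWI IP and -0.58 in total, but these cover 8 and 24 genes. Over the same 8 genes the total median was -0.02, and the MIWI median lay at percentile 20.8 of random lists and at 0.02 after the shift. The meiosis and spermatocyte median was 0.44 over 11 genes in the MIWI IP and 0.99 over 5 genes in the MILI IP against -0.40 over 24 in total. Over the same genes the total median was -0.51 for the MIWI IP and -0.08 for the MILI IP.

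Repeat families with inserts over 20 nt also parted between sample types, and these differences were not tested either. ERV1 antisense had ratios of 1.49 in the MIWI IP and 1.21 in the MILI IP against 0.734 in total, and ERV1 sense 1.66 and 1.26 against 0.938. ERVK sense had 2.34 and 1.87 against 0.745, and ERVL antisense 1.63 and 1.61 against 0.894. MaLR antisense had 1.30 and 1.04 against 0.721, and MaLR sense 1.95 and 1.51 against 0.965. B4 sense had 1.26 and 1.19 against 0.847. In the MILI IP B4 antisense had 1.22 against 0.777 in total and ID antisense 1.32 against 0.536. Per gene-assigned read the MILI values of ERV1 sense and antisense, MaLR antisense, B4 sense and antisense and ID antisense lay below 1.

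Signals outside the main measurement lay above the 3 reads that a count of 0 allows. Reads of 20 to 23 nt on miRNA hairpins numbered 10993 in het total, 6237 in hom total, 151 in the het MIWI IP, 398 in the hom MIWI IP, 238 in the het MILI IP and 337 in the hom MILI IP. Reads on the mitochondrial chromosome numbered 9706 in het total, 18226 in hom total, 19 and 55 in the MIWI IPs, and 36 and 64 in the MILI IPs, het before hom.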

How the results depend on the processing

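The alternatives by insert length, by piRNA cluster or repeat label, by denominator, by distinct ends for the cluster share, and by thinning for the overlap were chosen after seeing the data, and the others were fixed before the data were examined. No paired analysis was run, because each group had 1 library and sample types are not replicates of each other. With 1 library per group, no library could be left out. The shares of bases at positions 1 and 10 of reads and the 3 alternatives for them were not run, since they need sequences or the mm9 genome. Among summary results 67 values kept their direction and size under an alternative, 109 moved beyond their counting interval or 1.5 times a count, and 5 reversed. For named genes 552 values kept direction and call or, where the gene was not called, stayed within its counting interval. Of the others, 17 kept direction but lost the call, 14 of genes not called moved beyond that interval and 1 reversed. For gene lists 73 medians kept their place, the genic precursor median of the MIWI IP left the lowest 2.5% by distinct ends (-0.84) and that of the MILI IP entered it (-1.18), which made 2 MILI lists beyond the middle 95% in place of 1. The cause was not tested.

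Counts of genes changed with each threshold by construction. With at least 500 reads, hom total had 1543 higher and 928 lower genes, the MIWI IP 9 and 18, and the MILI IP 7 and 18. With at least 20 reads, the MIWI IP had 545 and 533 and the MILI IP 563 and 236. At 1.5-fold, 2473 genes were lower in total, 366 higher in the MIWI IP, and 299 higher and 104 lower in the MILI IP. At 4-fold there were 882 and 461 in total, 12 and 48 in the MIWI IP, and 3 and 10 in the MILI IP.

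By distinct 5′ ends, 1570 genes were higher and 968 lower in total, 53 and 82 in the MIWI IP, and 24 and 26 in the MILI IP. Of these, 1551 and 833 in total, 51 and 80 in the MIWI IP, and 24 and 22 in the MILI IP were among the genes called by reads. Median of ratios scaling left 69 genes higher in the MILI IP. With inserts of at least 40 nt alone, 81 genes were lower in the MIWI IP, and 13 were higher and 10 lower in the MILI IP. With reads free of a cluster or repeat label, 77 genes were higher in the MILI IP. 1700006A11Rik reversed to 1.40 in the MILI IP with inserts of at least 40 nt. The cause was not tested. With windows of 5 kb, of the 20 windows with most hom reads 1 was lower and 6 were higher in the MIWI IP and 0 were lower in the MILI IP. Counts with the most covered end left out, with either strand or with all placements stayed within 1.5 times the main count in all 3 comparisons.

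The cluster sense ratio stayed below 1 under every alternative. In total, MIWI IP and MILI IP it was 0.533, 0.744 and 0.801 with 1 placement, 0.611, 0.781 and 0.821 at 24 to 32 nt, and 0.799, 0.855 and 0.590 from 40 nt. By distinct ends it was 0.683, 0.637 and 0.649, per gene-assigned read 0.443, 0.618 and 0.4996, and per library read 0.463, 0.716 and 0.631. The L1 sense ratio of all inserts, 1.95, 1.43 and 1.76, stayed above 1 under every alternative. It was 1.74, 1.51 and 2.11 with 1 placement, and as a share within a length class 2.08, 4.48 and 5.96 over 20 nt, 7.82, 11.3 and 10.01 at 24 to 32 nt, and 1.29, 1.19 and 1.65 from 40 nt. Per gene-assigned read it was 1.72, 1.201 and 1.23, and per library read 1.79, 1.39 and 1.55. Except within length classes, these values include the L1MA5 end with inserts of 15 to 16 nt on average. Of transposon sense reads with 1 placement, that end held 16295 of 41259 in the het and 35997 of 94028 in the hom MIWI IP. In the MILI IPs it held 19490 of 51282 and 32528 of 91297. The cause was not tested.

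The 10 nt overlap depended on how ends were counted. Weighted by reads, it was 7.41 in het total and 11.8 in hom total but reversed in all IPs, to 0.0496 (het MIWI), 0.192 (hom MIWI), 0.0345 (het MILI) and 0.123 (hom MILI). With 1 placement it was 1.49 in het total, 1.52 in hom total, 2.40 in the hom MIWI IP and 2.10 in the hom MILI IP, and the het MILI IP reversed to 0.974. With libraries thinned to the shallowest it was 3.62 and 4.28 in total, 4.24 in the hom MIWI IP and 3.34 in the hom MILI IP. Over 20 nt it was 1.94 and 2.48 in total, 3.92 in the hom MIWI IP and 3.34 in the hom MILI IP. The cause was not tested.

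The share of ends in common moved with depth and insert length. In the order het MIWI, hom MIWI, het MILI and hom MILI, the share of IP ends found in total was 20.6%, 19.2%, 22.3% and 18.5% after thinning, and 80.5%, 74.9%, 73.8% and 67.1% for ends with at least 2 reads. It was 65.6%, 51.7%, 55.0% and 46.0% at 24 to 32 nt and 57.2%, 59.4%, 52.5% and 55.4% from 40 nt. After thinning and for ends with at least 2 reads, 18.1% and 45.4% of het total ends lay in hom total, 21.5% and 52.8% of het MIWI ends in the hom MIWI IP, and 29.1% and 54.6% of het MILI ends in the hom MILI IP. For MIWI ends in the MILI IP the shares were 16.6% and 43.3% in het and 15.6% and 28.7% in hom. By distinct ends the 3′UTR share was 30.6% in het total, 29.3% in hom total, 15.4% and 18.0% in the MIWI IPs, and 31.6% and 28.3% in the MILI IPs. Genes higher in the het MIWI IP than in total numbered 648 by median of ratios scaling and 640 by distinct ends, in place of 1032. The cause was not tested. Depth limited the IPs most, with a floor of 14.3 RPM in the het MIWI IP and 20.4 RPM in the het MILI IP against 0.270 RPM in het total.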

Other observations

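Both hypotheses in this part and their tests were chosen after the overlap of 5′ ends was seen. The first was that L1 transcripts are cleaved opposite piRNA-sized RNAs more often in hom. It predicts that ends of piRNA-sized IP inserts and ends of total RNA inserts of at least 40 nt in L1, on opposite strands, overlap by 10 nt more often in hom. Pairs at 10 nt over the mean of other overlaps were 4.66 (3.58 to 5.99) for the het MIWI IP and 7.13 (6.65 to 7.64) for the hom MIWI IP, and 4.01 (3.12 to 5.11) for the het MILI IP and 5.75 (5.36 to 6.18) for the hom MILI IP. These pairs are not independent, because a sequence on several L1 copies counts at each of them. With 1 placement for both ends the values were 5.84 (3.78 to 8.75) for the het and 4.14 (3.32 to 5.12) for the hom MIWI IP, and 4.16 (2.70 to 6.21) for the het and 4.13 (3.196 to 5.28) for the hom MILI IP, so hom was not above het there. These counts do not settle the hypothesis.

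The second hypothesis was that mRNA ends opposite piRNA-sized RNAs are more frequent in hom. For ends in sense exons free of repeat and cluster labels with 1 placement, the value was 1.91 (1.39 to 2.57) for the het and 1.88 (1.54 to 2.28) for the hom MIWI IP, and 1.98 (1.58 to 2.46) for the het and 1.81 (1.54 to 2.11) for the hom MILI IP. A higher value in hom was not seen: hom was not above het in either IP, and the intervals overlapped. The value is relative to other overlaps and does not measure how frequent such ends are. Pairs at 10 nt numbered 47 and 112 in the MIWI IPs and 87 and 176 in the MILI IPs, het before hom, without scaling to depth. With so few pairs a moderate rise stays open, and the hypothesis is not settled.

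For clusters free of repeat labels the same count was 4.74 in the het and 4.33 in the hom MIWI IP, and 3.78 in the het and 3.69 in the hom MILI IP. Hairpin reads of mmu-mir-34c numbered 3349 in het total and 1768 in hom total. Those of mmu-mir-130b numbered 113 and 196 in total, 247 and 550 in the MIWI IPs, and 353 and 510 in the MILI IPs, het before hom.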
